A study of Mus musculus with 18 samples.

How the data were processed

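RNA from skin and pituitary of C57BL/6 mice was measured on 18 Clariom S arrays, a mouse platform of Affymetrix that reads most genes with a single probe set. Each tissue was sampled from wild-type mice, from mice lacking the long noncoding RNA of the MIR205HG locus (lncKO below) and from mice lacking the microRNA miR-205 (miR-205 KO below), with 3 arrays in each of the 6 groups. All mice are labelled as female and 5 to 6 weeks old. Samples are named below by group and by their number in the labels, which runs from 1 to 9 in skin and from 10 to 18 in pituitary. No number recurs, so no samples were paired. Per the labels' protocols, total RNA was extracted with a column kit from frozen tissue and turned into labelled single-stranded cDNA after amplification. The same extraction text, which speaks of ear tissue, stands beside the pituitary samples as well.

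The authors deposited a table with 1 intensity per probe set and array, on a linear scale in whole numbers. The background correction, summarisation and normalization that made these intensities are not given in the sources used here. The table holds 22206 probe sets with values from 4 to 1243875. The median intensity per array lay between 82 and 96, and between 22.8% and 25.3% of the probe sets of an array were at or below an intensity of 16. No more than 5.49% of the values were identical between any pair of arrays, so no array was treated as a repeat of another. For the platform, 19572 probe sets carried exactly 1 gene symbol, 0 carried several and 2634 had none in the table used to name them. Symbols were updated by gene ID through a RefSeq gene table of the assembly GRCm38.p6, in which all 19572 matched. The named probe sets stand for 19505 genes, of which 55 have more than 1 probe set. No genome build is named for the intensities, so no coordinates are given, and the RefSeq table served only for names and for the order of neighbouring genes. No probe set named here measures the MIR205HG transcript or miR-205 itself, so the genotypes are those of the labels.

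Intensities were log2 transformed without a pseudocount, as no value was 0, and were not normalized again. The test of each comparison was limma's linear model with empirical Bayes moderation (limma 3.58.1 in R 4.3.3, default settings), two-sided, with Benjamini-Hochberg adjustment over the 19572 probe sets named, and a threshold of 0.05 on the adjusted p. The 9 arrays of a tissue entered a single fit with a term per group, which leaves 6 residual degrees of freedom. The difference of a knockout effect between tissues was tested as an interaction in a fit of all 18 arrays. Every adjusted p for a gene comes from limma. Errors beside log2 fold changes are standard errors from that fit, with n = 3 arrays per group, and errors beside log2 intensities are SDs. The labels do not say that samples of a group came from separate mice, so the p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision. The median standard error of a log2 fold change was 0.26 in skin, 0.21 in pituitary and 0.34 for the interactions.

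The gene lists, the tests, the rule for named genes and most alternatives were fixed before the data were examined. There were 36 lists, covering cell types of both tissues and of tissues that a dissected piece could also hold, cellular processes, published targets of miR-205 and neighbours of the locus. Each list was tested with limma's camera at a preset inter-gene correlation of 0.01, using for each gene the probe set with the highest mean, with Benjamini-Hochberg adjustment over the 36 lists of a comparison. The camera test was repeated with a correlation estimated from the arrays, and fry, a rotation test of whether members move on balance one way, was run beside it. Counts of list members past the threshold are given over all probe sets and adjusted over the list alone. The genes named were, in each knockout comparison with wild type, the 6 highest and the 6 lowest log2 fold changes among genes past the threshold whose 3 knockout arrays all lay on one side of the 3 wild-type arrays (a separation that chance gives to 10% of genes). Up to 4 members per list past the threshold by smallest p were added, together with a set planned in any case. In pituitary that set was hormone genes, the receptor of growth hormone releasing hormone and the transcription factor genes Pou1f1 and Zbtb20. In skin it was keratins, Lef1 and published targets. Values for Pou1f1, Zbtb20 and Zeb2, and for Krt15 in miR-205 KO skin, are not given below. In the remaining comparisons the 3 highest and the 3 lowest genes past the threshold were named. At least 3 genes passed in each direction in each of these comparisons except lncKO against miR-205 KO in skin, where none was named.

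Both knockouts of a tissue were compared with the same wild-type arrays. The correlation and covariance of their fold changes, over genes, were therefore set against 100 simulated draws. Each draw built unchanged groups, the shared control among them, from random mixes of the arrays' deviations from their group means. The observed wild-type means entered no draw, so the draws do not hold the position of these wild-type arrays fixed. Overlaps of calls were set against the product of both counts divided by the number of probe sets. The fit was tested on simulated data with 200 changed genes among 19572 probe sets. The simulated values were drawn independently from normal distributions with the moderated variances. Correlation between genes and array effects were left out, so recovery and false calls on the real arrays may differ. For changes of 1 on the log2 scale it recovered 36% in skin for lncKO, 41% in skin for miR-205 KO and 35% for the direct comparison of both in skin. In pituitary it recovered 64%, 73% and 62% of such changes for the same comparisons. Of changes of 2 on the log2 scale it recovered 97% to 100% within a tissue. For the interactions it recovered 6% and 14% of changes of 1, and 88% and 87% of changes of 2, for lncKO and miR-205 KO. The calls on unchanged genes numbered between 6 and 11 per comparison.

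The alternatives were a filter keeping probe sets above the 40th percentile of mean signal, all probe sets of the table including those without a name, quantile normalization, centring of each array on its median, a variance trend with robust estimation, array weights, a fit of only the groups compared, a fit of all 18 arrays, a threshold of an unadjusted p under 0.05 with a change of at least 1.5-fold, and leaving out each array in turn. After the data were seen, a floor that set intensities under 16 to 16 was added, alone and with a filter keeping probe sets above 16 on most arrays. A planned test of genes with seed sites for miR-205 in their 3' UTR was not run, since no transcript sequences were used here.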

Results

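Gene expression was measured in skin and pituitary of wild-type, lncKO and miR-205 KO mice on 18 arrays, 3 per group, with the aim of comparing both knockouts in an epithelium and in an endocrine gland. The log2 intensities of skin arrays correlated with each other at r = 0.970 to 0.993, those of pituitary arrays at 0.987 to 0.993, and those of skin with pituitary arrays at 0.781 to 0.819. These are Pearson correlations across genes, which are not independent replicates. Within skin, wild-type arrays correlated with each other at 0.983 to 0.987 and with knockout arrays at 0.970 to 0.978, while lncKO and miR-205 KO arrays correlated with each other at 0.988 to 0.992. Genes of the Y chromosome separated the tissues. Kdm5d, a histone demethylase gene, lay at a log2 intensity of 2.77 ± 0.21 in skin and 7.93 ± 0.27 in pituitary (SD, n = 9 per tissue). Eif2s3y lay at 2.59 ± 0.37 in skin and 10.15 ± 0.52 in pituitary, and Uty at 3.18 ± 0.36 and 10.99 ± 0.10. For each of these genes the lowest pituitary array lay above the highest skin array, in samples whose labels all give the sex as female. These values argue against that label for the pituitary samples.

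**Figure D1:**
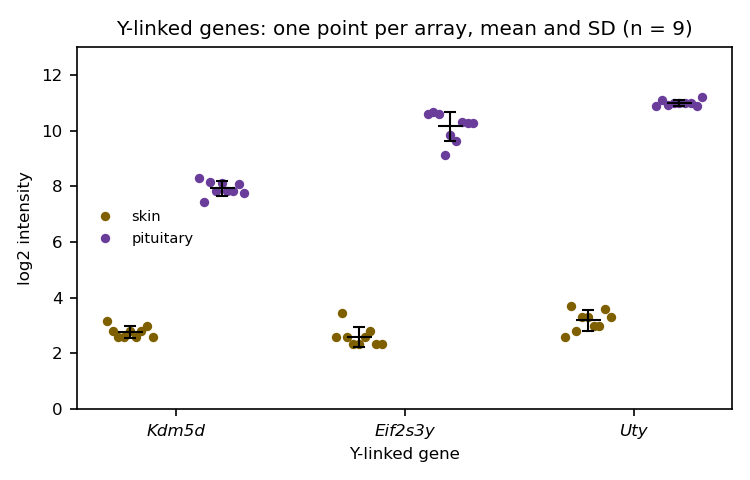
Log2 intensity of Kdm5d, Eif2s3y and Uty, one point per array, with the mean and SD over the 9 arrays of each tissue. Skin arrays lie between 2.32 and 3.70 and pituitary arrays between 7.43 and 11.19.

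The first comparison asks which genes of the skin differ when the noncoding RNA is missing. In lncKO skin, Scd3, Serpinb6d and Bglap had the highest log2 fold changes and Krtap7-1, Usp51 and Gh the lowest among genes whose 3 knockout arrays all lay on one side of the 3 wild-type arrays. Scd3, a fatty acid desaturase of sebaceous glands, rose by 4.23 ± 0.74 on the log2 scale (limma, adjusted p = 0.00299), from 11.06 ± 1.26 in wild type to 15.29 ± 0.97 in lncKO. Bglap, which encodes the bone protein osteocalcin, rose by 3.91 ± 0.24 (adjusted p = 5.545e-06), Serpinb6d, a serpin gene, by 4.07 ± 0.42 (adjusted p = 1.54e-04), and Col9a3, a chain of the cartilage collagen IX, by 3.53 ± 0.33 (adjusted p = 8.805e-05). The major urinary protein genes Mup22 and Mup2 rose by 3.85 ± 0.87 and 3.68 ± 0.91 (adjusted p = 0.0116 and 0.0170). Usp51, a deubiquitinase gene, had a fold change of -5.13 ± 0.21 on the log2 scale (adjusted p = 5.52e-08), with 8.19 ± 0.22 in wild type and 3.06 ± 0.10 in lncKO. The lncKO arrays read 8 to 9 for Usp51, so the size of this change depends on values near background, and it was -4.19 with a floor at an intensity of 16. With that floor Krtap7-1 and Gh, named next, gave -5.02 and -3.46. The hair keratin-associated protein genes Krtap7-1 and Krtap8-1 fell by 5.53 ± 1.06 and fell by 3.96 ± 0.80 on the log2 scale (adjusted p = 0.00501 and 0.00645). Ccdc92 fell by 4.23 ± 0.28 (adjusted p = 7.71e-06), Gm4559 fell by 4.21 ± 0.54 (adjusted p = 4.86e-04) and the growth hormone gene Gh fell by 4.42 ± 1.11 (adjusted p = 0.0185). In total 3009 probe sets passed the threshold, 1215 higher and 1794 lower in lncKO, of which 652 and 1116 differed by at least 2-fold. The split was 1539 higher and 1514 lower with quantile normalization, and 1499 and 1458 with each array centred on its median. Without lncKO 4 the count was 1886. Without wild type 1 the change of Gh was -2.50, and without wild type 3 that of Mup2 was 2.35. The call for Gh was lost without lncKO 4, 5 or 6 (adjusted p = 0.0522 to 0.0558) and that for Mup2 without lncKO 5 or 6 (0.0553 to 0.0656). A variance trend with robust estimation ended the calls for Mup22 (0.0794), Mup2 (0.1002), Krtap7-1 (0.0504) and Gh (0.107), a floor at an intensity of 16 ended these (0.0688 to 0.216) and that for Krtap8-1 (0.0712), and a fit of only the groups compared ended that for Gh (0.0518).

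The gene lists for hair, fat and cartilage passed in lncKO skin. The hair shaft and root sheath list, with 17 members measured, was lower (median log2 fold change -1.18, camera adjusted p = 0.00148). Its adjusted p was 0.748 with an estimated correlation. Wild type 1 and 2 carry this difference, with mean log2 intensities of the list of 6.56 and 7.09, whereas wild type 3 at 4.47 lies within the 4.36 to 4.93 of the 6 knockout arrays of both lines. Likewise Krtap8-1 read 648 and 1843 in wild type 1 and 2 and 82 in wild type 3, against 20 to 51 in the knockouts. Of the list members 4 fell, and 13 did adjusted over the list alone. Hoxc13, a regulator of hair keratins, passed as lower (adjusted p = 0.0125), but its mean was 3.91 in wild type and 2.73 in lncKO, both under an intensity of 16, and with a floor at 16 the change was -0.19 (adjusted p = 0.497). Tchh, which encodes the root sheath protein trichohyalin, fell by 3.36 ± 1.02 (adjusted p = 0.0418, and -5.06 without wild type 3), a call lost without wild type 1 or 2 or without any one lncKO array (0.0552 to 0.143), and with the variance trend (0.164), the floor (0.198) or a fit of only the groups compared (0.0877). Lef1, a Wnt pathway transcription factor of the hair matrix, fell by 1.02 ± 0.26 (adjusted p = 0.0193), which was lost without wild type 2, lncKO 4 or lncKO 5 (0.0567 to 0.0746), and with the floor (0.0522). The adipocyte list was higher (7 members, median 1.17, camera adjusted p = 0.00170, and adjusted p = 0.712 with an estimated correlation), with 4 members that rose and 5 that did adjusted over the list alone. Lep, the leptin gene, rose by 2.37 ± 0.40 (adjusted p = 0.00255) and the lipid droplet gene Cidec by 2.74 ± 0.56 (adjusted p = 0.00679, or 0.0672 with the floor). The cartilage list was higher as well (8 members, median 0.75, camera adjusted p = 0.00347, and adjusted p = 0.712 with an estimated correlation), with 4 members that rose and 4 that did adjusted over the list alone. Acan, which encodes the cartilage proteoglycan aggrecan, rose by 2.85 ± 0.37 (adjusted p = 5.18e-04) and Cnmd, the chondromodulin gene, by 1.51 ± 0.28 (adjusted p = 0.00412).

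Keratinocyte genes of lncKO skin went both ways. Of 14 measured genes of differentiated keratinocytes 4 rose and 2 fell, and the list did not pass (median -0.13, mean -0.04, camera direction up, adjusted p = 0.754). Dsg1a, a desmosomal cadherin gene, rose by 1.17 ± 0.23 (adjusted p = 0.00551), whereas Tgm1, which encodes a crosslinking enzyme of the cornified envelope, fell by 1.45 ± 0.22 (adjusted p = 0.00152). Krt10, a keratin of differentiating layers, rose by 0.94 ± 0.20 (adjusted p = 0.00832), but with quantile normalization the change was 0.45 (adjusted p = 0.140). The basal keratins Krt5 and Krt14 gave log2 fold changes of 0.03 ± 0.20 and 0.25 ± 0.20, and the stem cell keratin Krt15 of the hair follicle -0.25 ± 0.28, all short of the threshold (adjusted p = 0.930, 0.430 and 0.587). Skeletal muscle genes included Actn3, an actinin of fast fibres, which rose by 1.88 ± 0.34 (adjusted p = 0.00383), with 2 of 10 members past the threshold and a camera adjusted p of 0.256. Of 12 immediate early genes 3 fell, and 5 did adjusted over the list alone, among them Zfp36 by -2.18 ± 0.40 and Btg2 by -1.44 ± 0.28 (adjusted p = 0.00398 and 0.00515). The list had a camera adjusted p of 0.085. Fdft1, the squalene synthase gene, fell by 1.02 ± 0.21 (adjusted p = 0.00716), with 2 of 11 cholesterol synthesis genes lower. Among 14 published targets of miR-205, 1 rose over all probe sets and 1 adjusted over the list alone (median 0.25, camera adjusted p = 0.412). This was Prkce, a protein kinase C gene, by 1.09 ± 0.26 (adjusted p = 0.0147, but 0.0583 without lncKO 6). Zeb1, Inppl1, Inpp4b, Frk and Phlda3 did not pass, with log2 fold changes of -0.15 ± 0.24, -0.28 ± 0.27, 0.37 ± 0.27, 0.36 ± 0.32 and -0.43 ± 0.26. Of the 9 listed neighbours of the locus, G0s2 rose by 1.22 ± 0.39 (adjusted p = 0.0493) and 0 did adjusted over the list alone (camera adjusted p = 0.715). Without wild type 3 the change of G0s2 was 0.79. The G0s2 call was lost without wild type 2, wild type 3, lncKO 4 or lncKO 5 (0.0547 to 0.170) and in 6 alternatives (0.0507 to 0.170).

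**Figure D2:**
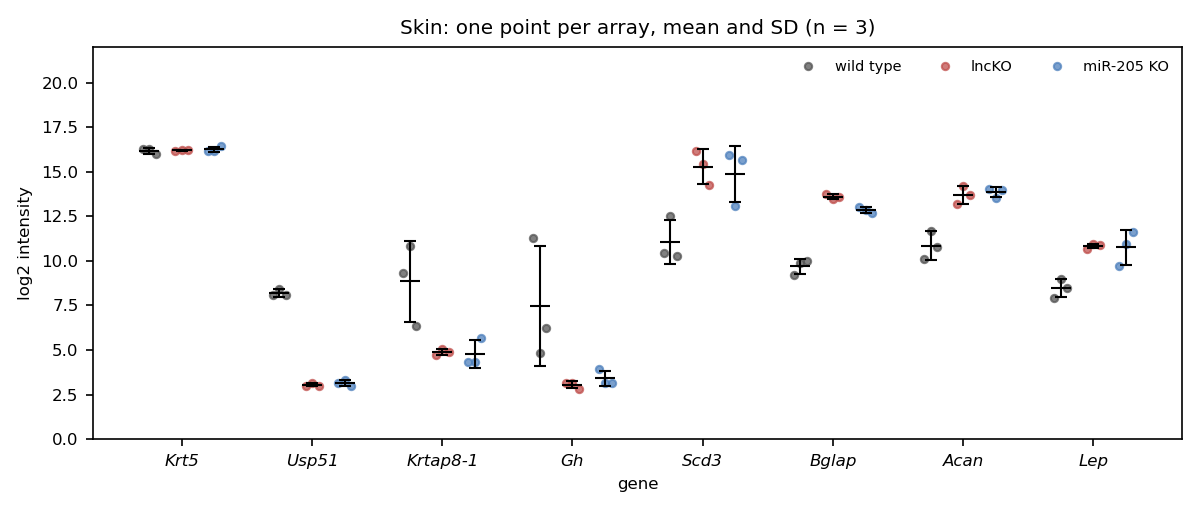
Log2 intensity of 8 genes in skin, one point per array, with the mean and SD of each group (n = 3). Krt5 lies near 16 in the 3 groups, Usp51 lies at 8.19 in wild type and at 3.06 and 3.16 in the knockouts, and Scd3, Bglap, Acan and Lep are higher in both knockouts.

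The second comparison asks which skin genes differ when miR-205 is missing. In miR-205 KO skin Scd3 and Serpinb6d again had the highest log2 fold changes and Krtap7-1 and Usp51 the lowest among genes with separated arrays. Scd3 rose by 3.82 ± 0.74 on the log2 scale (limma, adjusted p = 0.00501), Serpinb6d by 3.19 ± 0.42 (6.11e-04), Bglap by 3.16 ± 0.24 (2.85e-05), Cd300lf, a myeloid receptor gene, by 3.04 ± 0.35 (3.06e-04), Acan by 3.01 ± 0.37 (3.69e-04) and Nrep by 3.00 ± 0.40 (6.51e-04). Usp51 fell by 5.02 ± 0.21 (adjusted p = 7.22e-08), from 8.19 ± 0.22 in wild type to 3.16 ± 0.16 (-4.19 with the floor at 16, as the knockout arrays read 8 to 10), and Gm4559 fell by 4.87 ± 0.54 (2.1e-04). Krtap7-1, Krtap8-1 and Krtap19-9b fell by 5.73 ± 1.06, fell by 4.08 ± 0.80 and fell by 4.04 ± 0.99 (adjusted p = 0.00402, 0.00543 and 0.0158), and Gh fell by 4.05 ± 1.11 (0.0256). In total 3293 probe sets passed, 1328 higher and 1965 lower, of which 713 and 1180 differed by at least 2-fold. The split was 1643 higher and 1629 lower with quantile normalization, and 1677 and 1590 with median centring. The count was 1668 without miR-205 KO 7, 2127 without 8 and 2149 without 9. Without wild type 1 the change of Gh was -2.14. The call for Gh was lost without any one miR-205 KO array (0.0628 to 0.0758) and that for Krtap19-9b without wild type 1, wild type 2, miR-205 KO 7 or miR-205 KO 9 (0.0522 to 0.0551). With the floor at 16 Krtap7-1, Krtap19-9b and Gh gave -5.32, -3.19 and -3.46. The floor ended the calls for Scd3 (0.0606), Krtap7-1 (0.0567), Krtap8-1 (0.0641), Krtap19-9b (0.168) and Gh (0.208), the variance trend those for Krtap19-9b (0.0956) and Gh (0.127), and a fit of only the groups compared that for Gh (0.0633).

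The lists moved in miR-205 KO skin as follows. Hair shaft and root sheath genes were lower, again against wild type 1 and 2 rather than 3 (median -1.36, camera adjusted p = 0.00357, and adjusted p = 0.701 with an estimated correlation), with 3 of 17 that fell and 12 that did adjusted over the list alone. Without wild type 2 the camera adjusted p was 0.0693. Adipocyte genes were higher (median 1.11, camera adjusted p = 0.00240, and adjusted p = 0.701 with an estimated correlation), with 4 of 7 that rose and 5 adjusted over the list alone, Lep by 2.28 ± 0.40 and Cidec by 2.68 ± 0.56 (adjusted p = 0.00310 and 0.00715). The floor ended the call for Cidec (0.0693). Cartilage genes were higher (median 0.65, camera adjusted p = 0.0133, and adjusted p = 0.701 with an estimated correlation), with 3 of 8 that rose and 3 adjusted over the list alone, such as Cnmd by 1.58 ± 0.28 (adjusted p = 0.00323). Without wild type 1 the camera adjusted p was 0.0506. Among 14 genes of differentiated keratinocytes 4 rose and 2 fell (camera adjusted p = 0.656). Dsg1a rose by 1.13 ± 0.23 (adjusted p = 0.00622), and Krt10 by 0.97 ± 0.20 (0.00670), or 0.53 with an adjusted p of 0.0771 after quantile normalization. Tgm1 fell by 1.19 ± 0.22 (adjusted p = 0.00439), as did Casp14, a caspase of cornifying cells, by -1.52 ± 0.34 (0.0108, or 0.0635 with the floor). The interferon-related genes Bst2 and Rsad2 went apart, with a rise of 2.06 ± 0.23 for Bst2 and a change of -1.73 ± 0.30 for Rsad2 (adjusted p = 2.48e-04 and 0.00267). The growth factor gene Fgf18, named as a member of the hair follicle stem cell list, rose by 1.68 ± 0.33 (limma, adjusted p = 0.00550). That list did not pass with camera.

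Of the 14 published miR-205 targets measured, 1 rose and 1 fell in miR-205 KO skin over all probe sets, and 3 rose and 1 fell adjusted over the list alone (median 0.19, camera adjusted p = 0.369). The gene that rose was E2f1, a cell cycle transcription factor, by 1.27 ± 0.36 (limma, adjusted p = 0.0316), and this call was lost without any one of the 6 arrays (0.0527 to 0.0995) and with the floor at 16 (0.125). Phlda3, whose product restrains AKT signalling, fell by 1.23 ± 0.26 (adjusted p = 0.00809). Zeb1, Inppl1, Inpp4b and Frk did not pass, with log2 fold changes of -0.05 ± 0.24, 0.00 ± 0.27, 0.24 ± 0.27 and 0.27 ± 0.32. Krt5 and Krt14 gave 0.09 ± 0.20 and 0.06 ± 0.20, and Lef1 -0.26 ± 0.26 (adjusted p = 0.789, 0.867 and 0.533). Of 9 negative regulators of PI3K and AKT signalling 2 fell (median 0.17, mean -0.11, camera adjusted p = 0.812). Of the 9 listed neighbours of the locus 0 passed over all probe sets or adjusted over the list alone (camera adjusted p = 0.755). Cr1l, outside that list but among the 15 nearest named genes and chosen after its values were seen, fell by 0.86 ± 0.22 (adjusted p = 0.0209), a call lost without wild type 3 (0.0768), miR-205 KO 7 (0.0830) or miR-205 KO 9 (0.0645).

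The direct comparison of both knockouts in skin asks where loss of the host transcript and loss of the microRNA differ. Limma called 0 probe sets between lncKO and miR-205 KO skin, with a lowest adjusted p of 0.290 and 637 probe sets at an unadjusted p under 0.05, 334 higher and 303 lower in lncKO. Lef1 and Prkce, past the threshold only in lncKO against wild type, gave log2 differences between the knockouts of -0.76 ± 0.26 and 0.83 ± 0.26, and Phlda3, past it only in miR-205 KO, gave 0.80 ± 0.26, each with an adjusted p of 1. Of the 36 lists 0 passed with camera, and 0 with fry. A fit of all 18 arrays called 6 probe sets. Without lncKO 4 the count was 1, and lists passed without lncKO 5 (1 list), miR-205 KO 7 (1) and miR-205 KO 9 (3).

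Fold changes of both skin comparisons correlated across genes at r = 0.909, with a covariance of 0.374. Simulated unchanged groups set against a shared control, simulated as well, gave a median r of 0.487 and a highest of 0.932 in 100 draws. Their median covariance was 0.0370 and the highest 0.217. The observed covariance lay 0.337 above the simulated median. Both comparisons called 896 probe sets higher, against 82.4 for independent lists, and 1387 lower, against 180, and 0 in opposite directions. Part of these excesses may come from the shared wild-type arrays, which are too few to be split.

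In pituitary, the comparison of lncKO with wild type asks which genes of the gland differ without the noncoding RNA. Of the genes named, Doc2b, Mettl21e and Aqp11 rose and Slc38a6 and Crb1 fell in every fit that left out an array. Doc2b, a calcium sensor of vesicle release, rose by 2.71 ± 0.30 on the log2 scale (limma, adjusted p = 0.00301), from 7.86 ± 0.55 in wild type to 10.57 ± 0.39. Mettl21e, a methyltransferase gene, rose by 2.53 ± 0.26 and the water channel gene Aqp11 by 2.07 ± 0.22 (adjusted p = 0.00294 each). Slc38a6, of an amino acid transporter family, fell by 2.41 ± 0.24 (adjusted p = 0.00294) and the polarity gene Crb1 fell by 2.12 ± 0.24 (0.00301). Pdk4, a kinase that inhibits pyruvate dehydrogenase, rose by 3.06 ± 0.45 (adjusted p = 0.0123, but 0.0693 without wild type 12). The genes Baalc and Sstr2, the latter a somatostatin receptor, fell by 2.35 ± 0.32 and fell by 2.34 ± 0.31 (0.00917 and 0.00840), calls lost without wild type 12 (0.0529 and 0.0505). Zbtb16, a zinc finger transcription factor, rose by 1.88 ± 0.29 (0.0155), lost without wild type 11, wild type 12 or lncKO 13 (0.0521 to 0.0783). Slc43a1 rose by 2.17 ± 0.39 (0.0283) and Hapln1 fell by 2.11 ± 0.38 (0.0297). Slc43a1 was lost without wild type 10, wild type 12 or any lncKO array (0.0634 to 0.126), and Hapln1 without any wild-type array, lncKO 13 or lncKO 14 (0.0660 to 0.126).

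Hormone genes of lncKO pituitary did not pass. Gh was the highest value of each of the 9 pituitary arrays and Prl lay at 93.6% to 100% of it, so both probe sets sit at the top of the scale and no change, nor its absence, can be read from them. Cga, at 68.0% to 74.1%, is close to it. Log2 fold changes were 0.04 ± 0.18 for Tshb, 0.05 ± 0.15 for Cga, 0.44 ± 0.24 for Lhb, 0.42 ± 0.23 for Fshb and 0.12 ± 0.26 for Pomc, with adjusted p between 0.498 and 0.952. Ghrhr, the receptor for growth hormone releasing hormone, gave 0.29 (adjusted p = 0.617). Gonadotroph genes were higher as a list (7 members, median 0.44, camera adjusted p = 8.23e-04, and adjusted p = 0.510 with an estimated correlation), with 0 past the threshold and 3 adjusted over the list alone. Corticotroph genes were higher (4 members, median 0.82, camera adjusted p = 8.24e-04, and adjusted p = 0.366 with an estimated correlation), 2 over all probe sets and 3 adjusted over the list alone. Tbx19, the transcription factor of this lineage, rose by 1.69 ± 0.27 (adjusted p = 0.0171, lost without wild type 12, lncKO 14 or lncKO 15, 0.0690 to 0.0775). Crhr1, the receptor for corticotropin releasing hormone, rose by 1.01 ± 0.19 (0.0358, lost without wild type 11, wild type 12 or any lncKO array, 0.106 to 0.154). Genes of stem and folliculostellate cells were higher (7 members, median 0.45, camera adjusted p = 0.00420, and adjusted p = 0.366 with an estimated correlation), 1 over all probe sets and 1 adjusted over the list alone. This was Sox2, by 1.07 ± 0.18 (0.0204), a call lost without any one array other than lncKO 15 (0.0569 to 0.0951). Posterior lobe genes were higher (7 members, median 0.41, camera adjusted p = 0.0186, and adjusted p = 0.576 with an estimated correlation), 0 over all probe sets and 2 adjusted over the list alone. The posterior lobe call was lost without wild type 11 (0.0901) or lncKO 13 (0.165).

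Cholesterol synthesis genes were lower in lncKO pituitary (11 members, median -0.60, camera adjusted p = 4.17e-06, and adjusted p = 0.366 with an estimated correlation), with 1 that fell and 6 that did adjusted over the list alone. Idi1, an isomerase of the pathway, fell by 1.07 ± 0.21 (limma, adjusted p = 0.0429), lost without any one array other than wild type 10 (0.0839 to 0.164). Immediate early genes were lower (12 members, median -0.80, camera adjusted p = 2.55e-04, and adjusted p = 0.539 with an estimated correlation), 1 over all probe sets and 3 adjusted over the list alone. The nuclear receptor gene Nr4a1 fell by 2.81 ± 0.47 (adjusted p = 0.0191), lost without wild type 10, wild type 12, lncKO 13 or lncKO 14 (0.0523 to 0.0775) and with the variance trend (0.0838). Circadian clock genes were higher (14 members, median 0.55, camera adjusted p = 0.00925, and adjusted p = 0.510 with an estimated correlation), 1 over all probe sets, with 6 higher and 1 lower adjusted over the list alone, and the list was lost without wild type 11 (0.0801). Ciart, a repressor within the clock, rose by 1.41 ± 0.23 (adjusted p = 0.0186), lost without any one array other than wild type 12 (0.0543 to 0.0755) and in a fit of all 18 arrays. In total 137 probe sets passed, 67 higher and 70 lower, of which 57 and 64 differed by at least 2-fold. The count was 74 without wild type 11, 11 without wild type 12, and 44, 74 and 67 without lncKO 13, 14 and 15. The floor at 16 left 11 probe sets and ended the calls of the 17 genes named above as changed (0.0563 to 0.164), a fit of only the groups compared ended those for Zbtb16, Nr4a1, Tbx19, Crhr1, Sox2 and Idi1 (0.0534 to 0.0700), and a fit of all 18 arrays those for Slc43a1, Zbtb16, Crhr1 and Ciart (0.114 to 0.536). The floor alone gives many dim probe sets a variance of 0, which shifts the variance shared by the moderation. With the floor and its filter 202 probe sets passed, and these included 136 of the 137. The variance trend raised the count to 307, array weights to 207 and the filter on dim probe sets to 267.

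**Figure D3:**
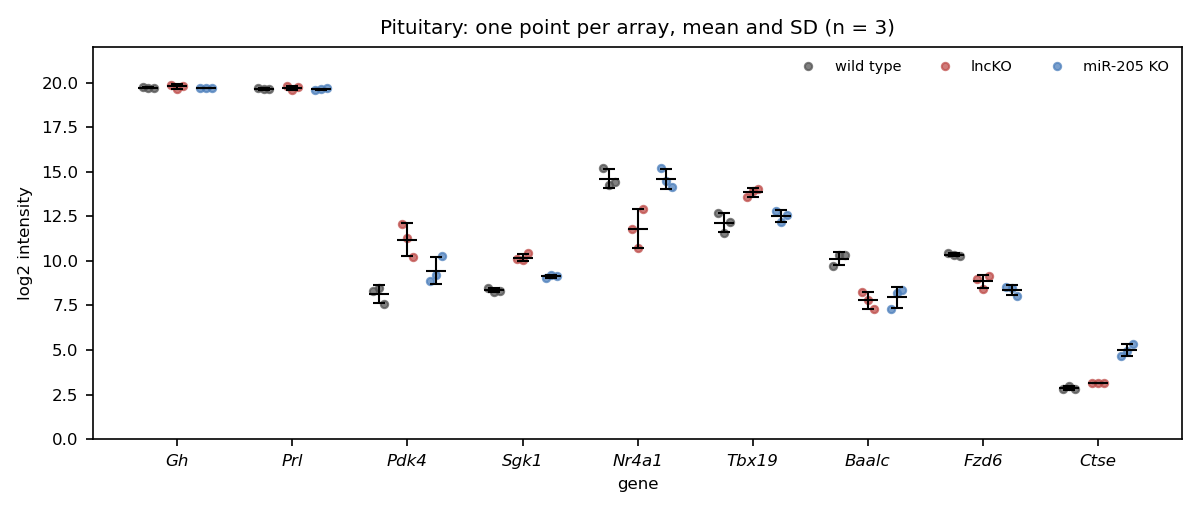
Log2 intensity of 9 genes in pituitary, one point per array, with the mean and SD of each group (n = 3). Gh and Prl lie at the top of the scale in each group, where no difference could be seen, Pdk4 is at 8.14 in wild type and 11.20 in lncKO, and Ctse is at 2.87 in wild type and 4.97 in miR-205 KO. Sgk1 was added after its values were seen.

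In miR-205 KO pituitary, the comparison with wild type asks what loss of the microRNA does to the gland. The chemokine gene Cxcl9, the meiotic cohesin gene Rec8 and the Wnt receptor gene Fzd6 fell, and Ctse, which encodes the protease cathepsin E, rose, each in every fit that left out an array. Cxcl9 fell by 2.85 ± 0.30 on the log2 scale (limma, adjusted p = 0.00371), from 6.53 ± 0.67 to 3.68 ± 0.28, and Rec8 fell by 2.42 ± 0.25 (0.00371). Fzd6 fell by 1.99 ± 0.22 (0.00479), from 10.34 ± 0.09 to 8.35 ± 0.29. Ctse rose by 2.10 ± 0.19 (0.00217), from 2.87 ± 0.11 to 4.97 ± 0.34, which is dim. With the floor at 16 the change of Ctse was 0.97 and that of Cxcl9 -2.53. The calls for Colgalt2 (1.60 ± 0.26, 0.0476), C1ql2 (1.37 ± 0.21, 0.0373) and Baalc (-2.18 ± 0.32, 0.0310) were lost without any one of the 6 arrays (0.105 to 0.255, 0.0520 to 0.190 and 0.0520 to 0.164). The calcium-binding protein gene Cabp7 (1.43 ± 0.20, 0.0264) and Uxs1, of UDP-xylose synthesis (1.28 ± 0.18, 0.0242), were lost without any one array other than miR-205 KO 16 (0.0782 to 0.127 and 0.0852 to 0.119). Hmcn1 (1.29 ± 0.20, 0.0373) was lost without any one array other than miR-205 KO 18 (0.109 to 0.199). The cell division gene Cdca3 (-1.94 ± 0.25, 0.0156) was lost without any one array other than wild type 10 (0.0556 to 0.0861), and the kallikrein gene Klk1 (-1.89 ± 0.30, 0.0458) without any one other than wild type 11 (0.105 to 0.224). Quantile normalization ended the call for Colgalt2 (0.0666), and a test of all probe sets, with or without a name, those for Colgalt2 (0.0528) and Klk1 (0.05003). A fit of only the groups compared ended these 8 calls (0.0650 to 0.117), and the floor at 16 ended these and the 4 before (0.0975 to 0.366).

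Hormone genes did not pass in miR-205 KO pituitary either, where Gh and Prl again sit at the top of the scale and show neither a change nor its absence, with log2 fold changes of 0.00 for Cga, which is close to it, 0.25 for Lhb, -0.01 for Fshb, -0.38 for Pomc and -0.04 for Ghrhr. Tshb, the thyrotropin beta gene, gave -0.73 ± 0.18 (limma, adjusted p = 0.303), and passed with the variance trend and robust estimation (0.0223). Proliferation genes were lower as a list (9 members, median -0.79, camera adjusted p = 1.88e-08, and adjusted p = 0.481 with an estimated correlation), with 0 past the threshold over all probe sets and 6 adjusted over the list alone. This list was dim in pituitary, with mean log2 intensities of 5.33 to 5.83 in wild type and 4.42 to 5.00 in miR-205 KO. Mki67, which encodes the proliferation antigen Ki-67, gave -1.78 ± 0.40 (adjusted p = 0.248) and the mitotic kinase gene Plk1 gave -1.09 ± 0.28 (0.361). Immediate early genes were higher (12 members, median 0.51, camera adjusted p = 4.1e-04, and adjusted p = 0.616 with an estimated correlation), 0 over all probe sets and 1 adjusted over the list alone. Gonadotroph genes were higher (median 0.33, camera adjusted p = 0.00290, and adjusted p = 0.616 with an estimated correlation), 0 over all probe sets and 3 adjusted over the list alone, and the list was lost without miR-205 KO 16 (0.125). Thyrotroph genes were lower (5 members, median -0.20, camera adjusted p = 0.0158, and adjusted p = 0.481 with an estimated correlation), 0 over all probe sets and 2 adjusted over the list alone, lost without miR-205 KO 17 (0.0576). Fibroblast genes (5 members, median -0.44, camera adjusted p = 0.0158) and genes of macrophages and dendritic cells (7 members, median -0.30, camera adjusted p = 0.0193) were lower, and clock genes (14 members, median 0.20, camera adjusted p = 0.0393) were higher, with 0 members each adjusted over the list alone. With an estimated correlation these had an adjusted p of 0.616, 0.481 and 0.616. The fibroblast call was lost without wild type 11 (0.272) or miR-205 KO 17 (0.0568), the macrophage and dendritic call without wild type 10 (0.0788), wild type 12 (0.0955), miR-205 KO 16 (0.125) or miR-205 KO 17 (0.0568), and the clock call without wild type 11 or 12 or any miR-205 KO array (0.0590 to 0.306). In total 21 probe sets passed, 8 higher and 13 lower, each by at least 2-fold. The count was 7, 6 and 4 without wild type 10, 11 and 12, and 8, 5 and 5 without miR-205 KO 16, 17 and 18. It was 0 with the floor at 16, 41 with the variance trend and 5 in a fit of only the groups compared. With the floor and its filter 19 probe sets passed, each of them among the 21.

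Immediate early genes differed between the knockouts in pituitary, where the comparison asks which genes separate loss of the noncoding RNA from loss of the microRNA. They were lower in lncKO (12 members, median -1.55, camera adjusted p = 1.71e-12, and adjusted p = 0.289 with an estimated correlation), 1 over all probe sets and 10 adjusted over the list alone. Nr4a1 lay at 11.80 ± 1.09 in lncKO and 14.61 ± 0.55 in miR-205 KO, a difference of -2.81 ± 0.47 (limma, adjusted p = 0.0364) that was lost without any one array other than lncKO 15 (0.0672 to 0.155). Slc5a8, a monocarboxylate transporter gene, differed by -2.51 ± 0.39 (0.0281, lost without lncKO 13, lncKO 15, miR-205 KO 16 or miR-205 KO 17, 0.0793 to 0.120), and C2cd4b by -2.54 ± 0.46 (0.0483, lost without any one array other than lncKO 15, 0.112 to 0.166). Klk1 was higher in lncKO by 2.33 ± 0.30 (0.0112, lost without lncKO 14, miR-205 KO 16 or miR-205 KO 17, 0.0597 to 0.0709). Cxcl9 was higher by 2.14 ± 0.30 (0.0151, lost without lncKO 13, lncKO 14, miR-205 KO 16 or miR-205 KO 18, 0.0606 to 0.0877) and Rec8 by 2.00 ± 0.25 (0.0112, lost without lncKO 14 or miR-205 KO 16, 0.0551 to 0.0645). Cholesterol synthesis genes were lower in lncKO (median -0.47, camera adjusted p = 8.52e-05), 0 over all probe sets and 4 adjusted over the list alone, and proliferation genes higher (median 0.68, camera adjusted p = 3.01e-05), 0 and 5. Their adjusted p was 0.363 each with an estimated correlation. The proliferation list was dim, at mean log2 intensities of 4.98 to 5.69 in lncKO and 4.42 to 5.00 in miR-205 KO. For that list the arrays of both knockouts overlapped. Higher in lncKO were also the lists of stem and folliculostellate cells (median 0.33, camera adjusted p = 0.00309), posterior lobe (0.40, 0.00547), fibroblasts (0.34, 0.00547), thyrotrophs (0.37, 0.0322) and corticotrophs (0.54, 0.0322). With an estimated correlation the adjusted p was 0.289 for the first of these and 0.363 for the rest. The thyrotroph call was lost with quantile normalization (0.0583) and without lncKO 13 (0.118), lncKO 14 (0.0622) or miR-205 KO 17 (0.0597), the corticotroph call without lncKO 13, lncKO 14, miR-205 KO 17 or miR-205 KO 18 (0.0505 to 0.0675), and the posterior lobe call without lncKO 13 (0.0807). In total 57 probe sets passed, 27 higher and 30 lower in lncKO, and the floor at 16 left 18 and ended the calls of the 6 genes named (0.101 to 0.223), while a fit of only the groups compared ended those for Nr4a1 and C2cd4b (0.0618 each), the variance trend that for Nr4a1 (0.115) and a test of all probe sets that for C2cd4b (0.0525). With the floor and its filter 98 probe sets passed, and these included 55 of the 57. The count was 14, 9 and 37 without lncKO 13, 14 and 15, and 4, 11 and 24 without miR-205 KO 16, 17 and 18.

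Both pituitary comparisons with wild type called 2 probe sets higher, Uxs1 (1.66 in lncKO and 1.28 in miR-205 KO) and Cabp7 (1.19 and 1.43), and 4 lower, Baalc, Fzd6 (-1.49 and -1.99), Adtrp (-1.86 and -1.49) and Tnr (-1.01 and -1.16). Independent lists would share 0.0274 and 0.0465, and 0 were called in opposite directions. Adtrp and Tnr were chosen after their values were seen. The correlation of fold changes across genes was 0.466. Simulated unchanged groups against a simulated shared control gave a median of 0.532 and a highest of 0.979 in 100 draws. The covariance was 0.0457 against a simulated median of 0.0303 and a highest of 0.115, a difference of 0.0154. Part of the overlap may come from the 3 shared arrays here too.

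**Figure D4:**
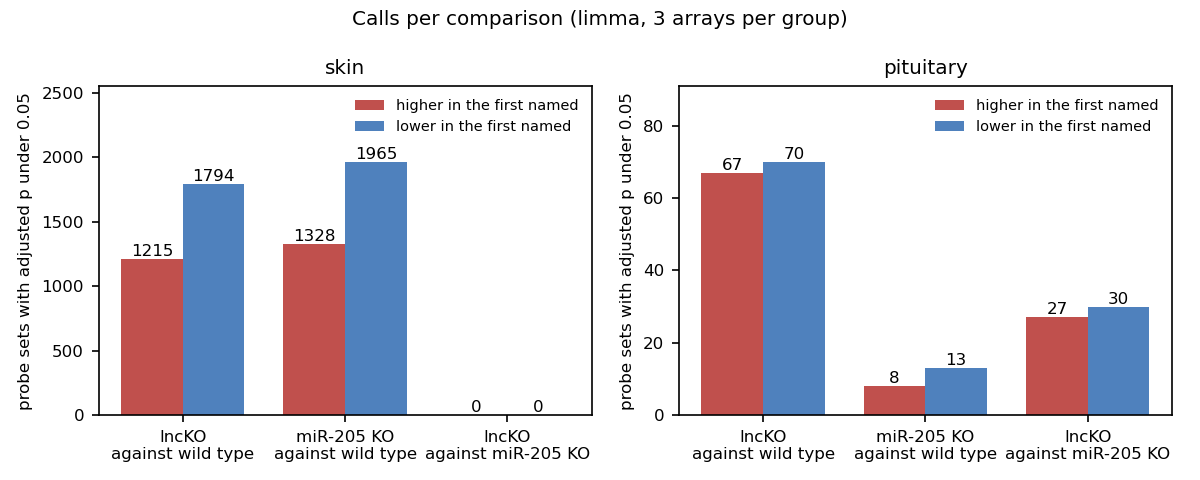
Number of probe sets past the threshold in each comparison (limma, 3 arrays per group), higher and lower in the group named first, for skin and pituitary on separate scales. Skin knockouts against wild type give 1215 and 1794, and 1328 and 1965, while the pituitary comparisons stay at 70 or fewer in a direction.

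The knockout effects were then compared between tissues, where the tissues also differ in the Y-linked genes given above. A difference of sex between the samples cannot be told apart here from a difference of tissue. Usp51 and Krtap7-1 had the most positive differences. For Usp51 the lncKO effect was higher in pituitary than in skin by 5.17 ± 0.27 on the log2 scale (limma interaction, adjusted p = 8.05e-10) and the miR-205 KO effect by 5.04 ± 0.27 (1.31e-09), or by 4.23 and 4.20 with the floor at 16, since Usp51 is near background in the knockout skin. For Krtap7-1 the differences were 5.32 ± 1.22 (0.0101) and 5.57 ± 1.22 (0.00757), and for Gm4559 4.68 ± 0.67 (2.84e-04) and 4.77 ± 0.67 (2.58e-04). The Scd3 effect was lower in pituitary, by -4.82 ± 0.87 for lncKO (0.00214) and -4.05 ± 0.87 for miR-205 KO (0.00675). Serpinb6d and Mup19, a major urinary protein gene, gave -4.20 ± 0.52 (7.75e-05) and -3.96 ± 1.00 (0.0174) for lncKO, and Bglap and Cxcl9 gave -4.03 ± 0.37 (3.31e-06) and -3.64 ± 0.43 (7.02e-05) for miR-205 KO. The variance trend and the floor at 16 ended the call for Mup19 (0.0546 and 0.0781). For lncKO 1811 probe sets passed, 1151 with a higher and 660 with a lower effect in pituitary, and for miR-205 KO 1948, 1225 and 723. Median centring moved the median of all effects by -0.10 and -0.13. The splits were then 864 and 838 for lncKO and 882 and 981 for miR-205 KO, and with quantile normalization 893 and 832, and 907 and 856. Without pituitary wild type 12 the lncKO count was 1174.

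Gene lists differed between tissues in the knockout effects as well. For lncKO, the effects on gonadotroph (median 1.10, camera adjusted p = 6.96e-04), posterior lobe (0.63, 0.0119) and hair genes (1.45, 2.89e-04) were higher in pituitary, and those on adipocyte (-2.07, 2.89e-04) and cartilage genes (-0.83, 7.17e-04) lower. With an estimated correlation the adjusted p was 0.335 for gonadotroph, 0.818 for hair and 0.368 for the other three lists. For miR-205 KO, gonadotroph (1.10, 0.00337), hair (1.27, 0.00350) and immediate early genes (0.99, 0.0331) were higher, and adipocyte (-1.46, 0.00296), cartilage (-0.83, 0.00350) and proliferation genes (-0.99, 0.00396) lower. Gonadotroph genes had an adjusted p of 0.504 with an estimated correlation and the other lists 0.600. The hair list had mean log2 intensities of 3.58 to 3.83 on the pituitary arrays, under an intensity of 16. Its differences therefore rest on the fall in skin. The gonadotroph list was near that level in skin, at 4.70 to 4.94 in wild type, 3.90 to 4.34 in lncKO and 3.99 to 4.16 in miR-205 KO. Part of its differences therefore rests on dim probe sets in skin. On the pituitary arrays the adipocyte and cartilage lists were dim as well, at 4.59 to 5.13 and 4.65 to 5.07. Their differences therefore rest largely on the rise in skin. The proliferation list was dim in pituitary, at 5.33 to 5.83 in wild type and 4.42 to 5.00 in miR-205 KO. The hair call for miR-205 KO was lost without skin wild type 2 (0.0625), and the immediate early call without skin wild type 1 (0.180), skin miR-205 KO 7 (0.104) or 9 (0.0760), pituitary wild type 11 (0.117) or pituitary miR-205 KO 17 (0.0639).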

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

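In this part the tests of why wild-type skin stood apart were chosen only after the result was seen, while the interactions and the counts over other splits of the arrays were planned. The knockout effects differed between pituitary and skin by limma's interaction test for 1811 genes in lncKO and 1948 in miR-205 KO. For lncKO the genes with the strongest differences were Krtap7-1 (5.32 on the log2 scale), Usp51 (5.17, or 4.23 with a floor at 16), Gm4559 (4.68), Scd3 (-4.82), Serpinb6d (-4.20) and Mup19 (-3.96). For miR-205 KO they were Krtap7-1 (5.57), Usp51 (5.04, or 4.20 with that floor), Gm4559 (4.77), Scd3 (-4.05), Bglap (-4.03) and Cxcl9 (-3.64). Of the genes named in the skin comparisons, 40 of 78 for lncKO and 43 of 81 for miR-205 KO passed this test, as did 12 of 25 and 9 of 20 of those named in pituitary. Over all probe sets 9.25% and 9.95% passed for lncKO and miR-205 KO. Many of the named genes were chosen for their change on these same arrays, so higher shares follow from that choice. The 2634 probe sets without a gene name were outside the comparisons above. In a test of all 22206 probe sets 433 of them (16.4%) passed for lncKO and 447 (17.0%) for miR-205 KO in skin, against 16 (0.607%) and 2 (0.0759%) in pituitary. Among probe sets with a gene name the shares in that test were 15.3%, 16.5%, 0.674% and 0.0817%.

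The arrays of each pair of groups within a tissue can be split in 10 ways, which are too few for a share under 0.05. In skin the real split called 3009 genes for lncKO and 3293 for miR-205 KO, with 1 of 10 splits as large in each case and a highest other count of 0. The direct comparison of the knockouts in skin called 0 genes in 10 of 10 splits. In pituitary the real splits called 137, 21 and 57 genes for lncKO, miR-205 KO and the direct comparison, with 1 of 10 splits as large each and a highest other count of 0. For the interactions 2 of 100 drawn splits were as large for lncKO (1811 genes, highest other 1834) and 1 of 100 for miR-205 KO (1948, highest other 1939). These shares lie under 0.05 for the arrays of both tissues split together, but the counts follow the skin groups: splits that mixed them called at most 5 and 8 genes, and of those that kept them 2 of 14 and 1 of 12 were as large. The draws reuse the 10 splits of the skin arrays, which are too few for a share under 0.05, as are the splits that kept the skin groups.

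Wild-type skin stood apart from both knockouts, which gave 0 calls against each other. A smaller share of keratinocytes in the knockout pieces would by itself raise the markers of other cell types alike. The gap between the mean log2 intensities of the adipocyte and endothelium lists was 4.31 ± 0.42 in the knockouts (SD, n = 6) and 2.85 ± 0.63 in wild type (n = 3). The exact two-sided permutation p was 0.0119, the smallest that 84 splits allow, so these lists did not rise alike. The adipocyte list had already been called higher on these arrays, so this p only repeats that result. A smaller share of keratinocytes beside other causes stays open. A difference in the wild-type arrays or their handling remains open. Probe sets of olfactory and vomeronasal receptors, which skin hardly uses, were called there in 7.64% of cases for lncKO (108 of 1414). For miR-205 KO skin the share was 7.92% (112 of 1414). Other skin probe sets of matched level were called in 12.6% and 13.5%, and all skin probe sets in 15.4% and 16.8%. In each pituitary comparison with wild type 0.0707% of the receptors were called. Matched probe sets were called there in 0.0326% and 0.0231%, and all probe sets in 0.700% and 0.107%. The contrast between tissues thus follows the number of calls and decides nothing about handling. Loss of miR-205 in both lines cannot be told apart from a difference in handling, because both knockouts share the same wild-type arrays and no label gives a batch. The list of published targets decides nothing here, with a lowest camera adjusted p of 0.369 and members that went both ways. The genotypes themselves and the amount of underlying fat, cartilage and muscle in each piece stay open as untested.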

How the results depend on the processing

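The floor at an intensity of 16 and its combination with a filter were chosen after the data were seen, and the other alternatives were planned. No direction past the threshold was reversed in any of them. Of the genes named as changed, 29 of 70 (skin lncKO), 27 of 73 (skin miR-205 KO), 0 of 17, 0 of 12 and 0 of 6 (pituitary lncKO, miR-205 KO and the direct comparison) and 5 of 6 and 6 of 6 (interactions) kept their calls in each alternative that tested them. Filters on dim probe sets left 8 of the 29, 8 of the 27 and 1 each of the 5 and 6 untested in some alternatives. Without each array 38, 37, 5, 4 and 0 calls were kept in the first 5 comparisons. Of 39 list calls 25 were kept without each array. The signal over background limits dim probe sets: the floor alone gives many of them a variance of 0, which shifts the variance shared by the moderation, and it ended 101 of 190 calls of named genes. Of the 162 that the floor with the filter also tests, the floor alone ended 85 and the floor with the filter 2. Quantile normalization ended 19, a fit of only the groups compared 42, the variance trend 18, and median centring 9.

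Counts of genes that moved by over 1.5 times were as follows, and the cause was not tested unless stated. With the filter on dim probe sets they were 1884 and 2164 in skin (lncKO, miR-205 KO), where fewer were tested, and 267 and 132 in pituitary (lncKO, direct comparison). The floor gave 1937 and 2173 in skin, and 11, 0 and 18 in pituitary (lncKO, miR-205 KO, direct comparison), and with its filter 98 for the last. The variance trend gave 307, 41 and 161 in pituitary, a fit of only the groups compared 59, 5 and 27, which has fewer degrees of freedom, and array weights 207 for lncKO. A fit of all 18 arrays called 6 genes between the knockouts in skin. With an unadjusted p and at least 1.5-fold, which is a looser threshold, the counts were 5268, 5472 and 425 in skin (lncKO, miR-205 KO, direct), 1289, 726 and 1113 in pituitary, and 4782 and 4973 for the interactions.

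Leaving out 1 array at a time, the counts ranged from 1886 to 2514 for skin lncKO (1886 without lncKO 4), 1668 to 2775 for skin miR-205 KO (1668, 2127 and 2149 without miR-205 KO 7, 8 and 9) and 0 to 1 for the direct comparison in skin (1 without lncKO 4). In pituitary they ranged from 11 to 123 for lncKO (74 and 11 without wild type 11 and 12, and 44, 74 and 67 without lncKO 13, 14 and 15), 4 to 8 for miR-205 KO (each array moving the count by over 1.5 times) and 4 to 37 for the direct comparison (each array likewise). For the interactions they were 1174 to 1847 (1174 without pituitary wild type 12) and 1322 to 2006. The number of lists past the threshold ranged from 3 to 5, 2 to 4 and 0 to 3 in skin, 5 to 8, 3 to 7 and 6 to 11 in pituitary, and 5 to 8 for each interaction. With an estimated correlation it was 0 in lncKO and miR-205 KO skin, in the 3 pituitary comparisons and in both interactions. With fry it was 9 and 9 in skin and 1, 0 and 2 in pituitary. The correlation of both knockouts' fold changes was 0.913 to 0.919 in skin and 0.520 to 0.576 in pituitary without a wild-type array, and 0.918 and 0.464 with the filter on dim probe sets. The test of seed sites was not run.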

Other observations

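In this part the tests of the keratin-associated family, the glucocorticoid and clock genes and the genes of chromosome 1 were chosen only after the result was seen, while the remaining genes, unless said otherwise, and the somatotroph list were planned. The family of hair keratin-associated proteins, which form the matrix around hair keratins, was lower in both knockouts of the skin. Of its 50 probe sets 32 passed as lower in lncKO and 36 in miR-205 KO, with 0 higher in either (limma), and median log2 fold changes of -2.28 and -2.49. With quantile normalization 31 and 35 were lower and with median centring 32 and 36, again with 0 higher. Wild type 1 and 2 carry this difference, with family means of 7.75 and 8.38 against 5.61 in wild type 3 and 4.76 to 5.52 in the knockouts. Leaving out 1 array gave 20 to 43 lower in lncKO (20 without wild type 2, 21 without lncKO 4, 20 without lncKO 6) and 21 to 44 in miR-205 KO (22 without wild type 2, where 1 was higher, and 21 without miR-205 KO 7). In pituitary 0 of the 50 passed in either knockout, but the family was near background there, with a median log2 level of 3.83. A fall could hardly be seen at that level, so the lack of calls decides nothing about a difference between the tissues. Angpt1, an angiopoietin gene, rose by 2.38 ± 0.29 in lncKO skin and by 2.48 ± 0.29 in miR-205 KO skin (limma, adjusted p = 4.175e-04 and 3.25e-04), and Icos, a costimulatory receptor of T cells, by 1.38 ± 0.24 and 1.51 ± 0.24 (0.00267 and 0.00159). In lncKO skin the interferon-induced genes Bst2 and Rsad2 went opposite ways, as Bst2 rose by 1.49 ± 0.23 and Rsad2 fell by 1.99 ± 0.30 (0.00159 and 0.00127).

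Some genes of pituitary and posterior lobe lists passed in skin, in both directions. Oxt, the oxytocin gene, fell by 2.17 ± 0.23 in lncKO and fell by 2.59 ± 0.23 in miR-205 KO from 7.72 ± 0.21 in wild type (limma, adjusted p = 1.74e-04 and 7.16e-05, n = 3). The transcription factor gene Pitx1 had log2 fold changes of -2.30 ± 0.26 and -2.41 ± 0.26 (2.35e-04 and 1.67e-04), or -1.77 in each with a floor at 16. Tshb rose by 1.34 ± 0.26 in lncKO and by 1.33 ± 0.26 in miR-205 KO (0.00579 and 0.00554). Intensities of Gh were 2501, 29 and 76 on the wild-type skin arrays and between 7 and 15 on the knockout arrays, where pituitary arrays gave 817571 to 966812, the highest value of each. Of 6 somatotroph genes 3 were lower in each knockout, 3 and 4 adjusted over the list alone, with a camera adjusted p of 0.131 and 0.119.

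Of 6 genes known to respond to glucocorticoids, chosen after their values were seen, 4 passed as higher in lncKO pituitary, and Klf9 (0.66 ± 0.18, adjusted p = 0.136) and Per1 (0.02 ± 0.31, 0.993) did not. Sgk1 rose by 1.82 ± 0.17 (limma, adjusted p = 0.00294, at most 0.0187 without an array), Fkbp5 by 1.60 ± 0.21 (0.00840, but 0.0505 without wild type 12), Tsc22d3 by 1.56 ± 0.21 (0.00927, but 0.0529 without wild type 12) and Zbtb16 by 1.88 ± 0.29 (0.0155, lost without wild type 11, wild type 12 or lncKO 13, at most 0.0783). Hormone exposure at collection may contribute, since a second list of 15 such genes had a median log2 fold change of 0.62 (0.53 to 0.72 without each array), 13 higher, and a camera p of 3.82e-09, or p = 0.00308 with an estimated correlation, with calls for Klf15 (1.42 ± 0.26, 0.0334, lost without wild type 11, wild type 12, lncKO 13 or lncKO 15, at most 0.126) and Ddit4 (0.86 ± 0.17, 0.0443, lost without any one array, at most 0.139). A different time of day at collection may contribute too, since the mean of Per1, Per2, Per3, Dbp, Tef, Nr1d1, Nr1d2 and Ciart minus that of Arntl, Npas2 and Clock was -0.14 ± 0.18 in lncKO and -1.47 ± 0.52 in wild type (SD, n = 3), a difference of 1.34 with the arrays of both groups apart, against 0.32 for miR-205 KO, although Per1, which belongs to both sets of genes, showed no call. In miR-205 KO pituitary the second list also leaned higher, with a median of 0.29 and a camera p of 0.00153, or p = 0.0424 with an estimated correlation, but 0 calls, and both explanations stay open beside an effect of the genotype, which is untested.

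Genes of chromosome 1, which carries the locus, were frequent among the calls in miR-205 KO pituitary, with 7 of 21 (33.3%) against 5.56% of the probe sets tested (one-sided Fisher's exact test, p = 9.448e-05), but not in lncKO pituitary, whose line is altered at the same locus (7 of 137, 5.11%, p = 0.645), nor in lncKO skin (5.88%, p = 0.215), with 6.23% in miR-205 KO skin (p = 0.0395). The excess is not stable, since leaving out 1 array left 4 to 8 calls with 1 to 2 on the chromosome, Ctse each time with Uxs1 or Hmcn1 at most (one-sided Fisher's exact test, p = 0.205 to 0.330 without wild type 10, 11 or 12 or miR-205 KO 17, 0.0693 without miR-205 KO 16 and 0.0276 without miR-205 KO 18). The genes are C1ql2, Ctse, Colgalt2, Uxs1, Hmcn1 and, named after their values were seen, Tnr and Ifi204 (-1.16 and -1.04 on the log2 scale), of which 4 went the same way in miR-205 KO skin and 3 passed there, Ctse and Tnr in the same direction (2.58 and -1.05, limma, adjusted p = 0.00267 and 0.00820) and Hmcn1 in the opposite one (-0.81, 0.0208). The 7 genes lie 141 to 907 named genes from the locus, so these calls are not of its nearest genes. The distance was made the test only after it was known, so it decides nothing about an effect of the deletion on those genes. The 0 calls among the 15 nearest decide nothing either, as 98.5% of runs of 15 neighbouring probe sets hold none. Alleles of a donor strain around the locus may contribute and cannot be told apart from other causes, as 0 of the 7 lie among the 100 nearest, a condition that was added to the donor-strain test after its result had been seen and without which the excess would have met that explanation.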
